A study of Arabidopsis thaliana with 23 samples.

How the data were processed

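The series held 11 mRNA and 12 small RNA libraries of whole Arabidopsis seedlings. Wild-type seedlings, named gl1 in the design text, and sos2-2 mutants grew on MS medium with sucrose at 22 °C for 10 days after 2 days in the cold. The salt groups then spent 12 hours in liquid MS with 100 mM NaCl. The labels do not say whether the MS groups were moved to liquid medium too. Groups and replicate numbers came from the sample titles. Each group held 3 libraries per assay, except the mRNA of sos2-2 on MS, for which 2 libraries were analysed. Columns of both tables were matched to samples by name. Deviations from the group means correlated for all 3 same-numbered pairs of wild type on MS and in NaCl in small RNA (r = 0.271, 0.215 and 0.172). The numbers were therefore taken to pair the libraries of that comparison, by the values and not by the labels. Its p-values still come from the fit without a replicate block, unless a block is named. Counts with the block, fitted over all groups, stand beside the main counts where they differ by over 1.5 times. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

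The mRNA values were TPM per transcript as deposited by the authors. Per the submitters' processing notes the tools included kallisto 0.46.2 and sleuth 0.30.0, with the genome build TAIR10, and the role of sleuth is not given in the sources used here. Each column summed to 1000000 over 48359 transcripts, plastid and mitochondrial transcripts included. TPM keeps no depth, so the depth of the mRNA libraries is unknown. TPM values were summed to 27655 genes, of which 27445 matched a locus of the TAIR10.1 RefSeq annotation that gave symbols and coordinates. Because the total is fixed, a larger plastid share lowers the TPM of every other gene. Close relatives such as LTP3 and LTP4, GSTU24 and GSTU25, LHCB2.1 and LHCB2.2 and the RBCS genes can exchange reads in such estimates, and the strandedness of the counting is not given in the sources used here, so genes that overlap another on the opposite strand are uncertain too.

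The small RNA values were RPM per mature miRNA as deposited by the authors, for 428 miRNAs in 215 families. Per the submitters' processing notes the tools included cutadapt and featureCounts 1.6.4, and the aligner is not given in the sources used here. The values of each column were whole multiples of 1 step, which gave back whole reads: 2737 of 2737 values between 1 and 200 reads lay within 0.1 of a whole number. The steps gave library totals of 16.7e6 to 19.6e6 reads, of which the listed miRNAs made up 83725 to 110760 RPM. Which reads the totals count is not stated. A value of 1 RPM thus stood for 16.7 to 19.6 reads, and members of a family with near-identical mature sequences can count the same reads, so families were tested too.

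The design fixed before the data were examined assumed that counts were possible and named limma for normalized values, and the values required that branch. Genes, miRNAs and families with a mean of at least 1 TPM or RPM over all libraries were tested, which left 16564 genes (16369 nuclear, 88 plastid and 107 mitochondrial), 293 miRNAs and 140 families. Values were taken to log2 after adding a pseudocount of 1, which understates the change of low genes. A single limma 3.58.1 fit with an intensity trend per assay held all groups, so that they shared 1 estimate of the spread, and gave 5 contrasts: salt in wild type, salt in sos2-2, sos2-2 against wild type on MS and in NaCl, and the interaction, which is the salt response of sos2-2 minus that of wild type, so a positive value can be a larger rise or a smaller fall. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The words rose and fell are used for called genes only. The median log2 change of all genes was −0.21, 0.16, −0.05, 0.32 and 0.39 in the 5 contrasts, and that of miRNAs was 0.10, −0.04, 0.01, −0.14 and −0.15. Every log2 change in the text is therefore relative to the median gene or miRNA, while adjusted p-values come from the values as deposited, and counts after median centring stand beside them.

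Gene lists were fixed before the data were examined: abscisic acid (ABA) and dehydration, SOS and ion transport, osmolytes, reactive oxygen species (ROS), small RNA machinery, photosynthesis, root markers, cell cycle, jasmonate, phosphate starvation and known miRNA targets. The miRNA lists were conserved families, young families (all others), copper, phosphate and sulfate, and triggers of secondary siRNAs. Photosynthesis genes and root markers also served as markers of the shoot and the root. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. fry, which asks whether a list changed at all and not whether it changed more than other genes, was run too. The named genes followed a rule also fixed beforehand: SOS2 and SE always, the 6 genes with the largest change in each direction among called genes with a mean log2 value of at least 2 and no overlap between the compared groups (the overlap condition does not apply to the interaction), and up to 2 called members per direction of each list, or the member with the smallest p where none was called. For miRNAs it took 5 per direction and every called family, and fewer were named where space was short, in order of the size of the change. A change described as the largest in the text is the largest under this rule. Family changes were set against the median change of their listed targets by Spearman's rho with 100000 permutations. Exact permutation tests were two-sided. Library purine trends are Spearman correlations across genes between a library's deviation from the mean log2 value and the purine share of the longest transcript, and 98.8% of tested genes had a purine share and a length.

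Alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, median centring, a fold change of at least 2, only the libraries compared, single transcripts, family sums, the replicate number as a block, leaving out each library in turn, and, for the relation of families to targets, the mean in place of the median and families with a mean log2 value of at least 5. Added after seeing the data were nuclear genes rescaled to a common total and filtered again (19686 tested), the 16369 tested nuclear genes with each library's nuclear total set to the mean, removal of each library's trend with purine share and length (loess, span 0.3) together with median centring, the library purine trend as a covariate, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered small RNA reads. DESeq2 was not run on TPM, which are not counts. The steps were tested on simulated data at the size of each contrast. For mRNA, limma recovered 95 to 98 of 100 simulated 4-fold changes and 44 to 62 of 100 2-fold changes in the contrasts of 2 groups, and 87 and 16 of 100 in the interaction, with 3 to 16 false calls. For small RNA it recovered at least 28 of 30 2-fold changes in each contrast. Simulated values varied independently from gene to gene, without shifts between libraries or correlation between genes. The simulated mRNA changes lay in genes with a mean log2 value of at least 2. Recovery and false calls in the real libraries, which do show such shifts, can therefore differ from these. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.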

Results

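The study measured mRNA and small RNA in whole Arabidopsis seedlings of the wild type and of sos2-2, a mutant of the kinase gene SOS2, on MS medium and after 12 hours in liquid MS with 100 mM NaCl. SOS2 belongs to the salt overly sensitive (SOS) pathway of sodium export, and SERRATE (SE) is a zinc-finger protein of miRNA processing. The series title places the 2 proteins together in keeping miRNA levels steady under salt. The 4 groups allow 5 comparisons: salt in each genotype, genotype in each medium, and the difference between the salt responses. The word salt stands for the whole treatment here. Since the labels do not say whether the MS groups were moved to liquid too, effects of NaCl and of the move cannot be told apart. Each group had 3 libraries per assay, except for 2 mRNA libraries of sos2-2 on MS.

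SOS2 (chromosome 5, 13634399 to 13638375, TAIR10.1) was expressed at 0.818 to 1.36 TPM in the 11 libraries and was not called in any comparison. Its mean was 1.08 ± 0.178 TPM in wild type on MS, 1.09 ± 0.145 in wild type in NaCl, 1.304 ± 0.0846 in sos2-2 on MS and 1.003 ± 0.258 in sos2-2 in NaCl (SD, n = 3, 3, 2 and 3). The labels do not say what the allele changes, so this level does not check the genotypes. SE (chromosome 2, 11572397 to 11576658) was at 15.9 ± 2.08, 13.2 ± 0.965, 12.8 ± 1.73 and 16.7 ± 3.98 TPM in the same groups and was not called either. Listed miRNAs together made up 98588 ± 13717 RPM in wild type on MS, 103951 ± 3450 in wild type in NaCl, 103030 ± 5899 in sos2-2 on MS and 98739 ± 7211 in sos2-2 in NaCl (SD, n = 3 each). None of the 4 comparisons of 2 groups passed an exact permutation test on these totals (p = 0.8, 0.5, 0.8 and 0.3, adjusted p = 0.8 for each, smallest p possible 0.1).

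Libraries differed in their makeup. Plastid transcripts took 68.3 ± 3.08% of the TPM in wild type on MS, 75.0 ± 3.97% in wild type in NaCl, 70.8 ± 3.08% in sos2-2 on MS and 67.9 ± 1.95% in sos2-2 in NaCl (SD, n = 3, 3, 2 and 3). The largest difference, between the genotypes in NaCl, had an exact permutation p of 0.1, the smallest that 3 against 3 allows (adjusted p = 0.4 over 4 comparisons). Libraries also differed in how their values followed the purine share of transcripts across genes, which are not independent. This Spearman correlation ranged from −0.391 to 0.326, was below 0 in the 3 wild-type libraries on MS (mean −0.242 ± 0.152, SD) and above 0 in the 2 sos2-2 libraries on MS (0.218 ± 0.0298, SD).

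**Figure D1:**
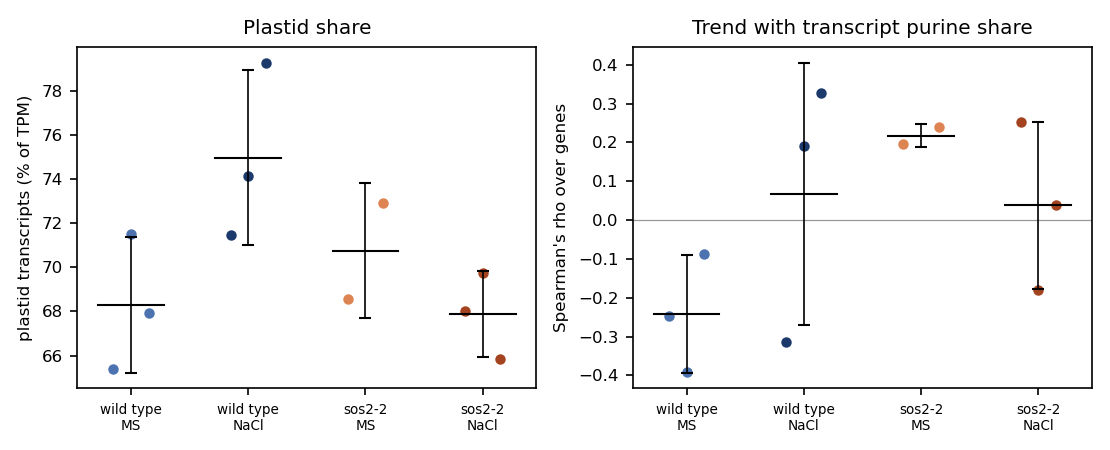
Share of TPM held by plastid transcripts (left, percent) and Spearman correlation across genes between each library's values and transcript purine share (right), per mRNA library. Points are libraries, long bars group means and whiskers SD. Wild type in NaCl spans 71.5 to 79.3% plastid transcripts, and the 2 sos2-2 libraries on MS lie above the 3 wild-type libraries on MS in the right panel.

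The first comparison asked how wild-type seedlings responded to salt. Of the ABA and dehydration list, 16 of 22 tested genes rose and 0 fell (19 rose when adjusted over the list alone), with camera adjusted p = 2.39e-36 and adjusted p = 0.00139 with an estimated correlation. Within it the cold-induced gene KIN1 went from 17.6 ± 4.17 to 235 ± 56.7 TPM (SD, n = 3 each, log2 change 3.87, SE 0.28, limma adjusted p = 4.48e-07), and COR15A, which encodes a protective protein of the chloroplast stroma, from 18.2 ± 2.68 to 231 ± 24.95 TPM (3.80, SE 0.36, 1.41e-05). The lipid transfer protein genes LTP4 (0.660 ± 0.264 to 65.5 ± 26.9 TPM, log2 change 5.47, SE 0.24, 5.57e-10) and LTP3 (5.04, SE 0.30) had the largest rises, followed by AT2G37870 (4.72, SE 0.36) and, after KIN1 and COR15A, AT1G16850 (3.53, SE 0.20). Photosynthesis genes fell, with 16 of 21 called lower and 0 higher (21 lower when adjusted over the list alone, camera adjusted p = 5.50e-11, adjusted p = 0.309 with an estimated correlation). After median centring 10 were called lower (14 adjusted over the list alone), and 8 when each library's purine and length trend was removed too. Among these the Rubisco small subunit gene RBCS2B went from 1193 ± 209 to 349 ± 93.1 TPM (−1.58, SE 0.26, 0.000435) and RBCS1B changed by −1.27 (SE 0.24).

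Osmolyte genes showed both directions. P5CS1, of proline synthesis, rose from 6.26 ± 0.186 to 30.4 ± 2.24 TPM (SD, n = 3 each, 2.32, SE 0.19, 2.55e-06) and GOLS1, of galactinol synthesis, rose by 0.88 (SE 0.21, 0.0494), while PRODH1, of proline breakdown, fell (−1.201, SE 0.22, 0.00073). The list of 8 was called upward (camera adjusted p = 0.00878, the same counts adjusted over the list alone, 4 higher and 1 lower after centring, adjusted p = 0.369 with an estimated correlation). Jasmonate genes were called upward too (0.00225, 0.369 with an estimated correlation), with 3 of 11 higher and 1 lower, also when adjusted over the list alone: the storage protein gene VSP2 (2.56, SE 0.31) and the lipoxygenase gene LOX2 (1.44, SE 0.23) rose, and the defensin gene PDF1.2A (−1.14, SE 0.37) fell. Cell cycle genes were called downward (0.000726, 5 of 9 lower and 8 adjusted over the list alone, 0.374 with an estimated correlation), among them CDC20.1 (−0.71, SE 0.20) and the kinase gene AUR1 (−0.71, SE 0.22). So was the ROS list (0.0263, 5 of 16 lower and 8 adjusted over the list alone, 5 after centring, 0.725 with an estimated correlation, and 0.0865 with the trend removed or 0.0683 with the purine trend as a covariate), led by the copper and zinc superoxide dismutase genes CSD2 (−0.89, SE 0.23) and CSD1 (−0.75, SE 0.28).

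Outside these lists, the cytochrome P450 gene CYP71A12, which acts in camalexin synthesis, went from 29.0 ± 17.9 to 0.421 ± 0.136 TPM (SD, n = 3 each, −3.98, SE 0.44, 2.20e-05). AT3G16530 (−3.34, SE 0.30), AT2G01379 (−3.30, SE 0.49), AT3G46880 (−3.24, SE 0.23), AT3G15356 (−3.05, SE 0.32) and AT1G15125 (−2.76, SE 0.28) also fell. The nitrate transporter gene NRT2.1 rose from 4.64 ± 1.14 to 16.4 ± 4.01 TPM (1.82, SE 0.21). The phosphate sensor gene SPX1 fell (−0.79, SE 0.24). The root marker and phosphate starvation lists were not called (camera adjusted p = 0.747 and 0.364, with 1 higher and 3 lower of 10, 1 higher and 0 lower after centring, and 1 lower of 7 adjusted over the list alone). The same held for SOS and ion transport (0.283, 0 of 15, 2 higher after centring), small RNA machinery (0.0878, 0 of 24) and known miRNA targets (0.351, 4 higher and 4 lower of 66 also when adjusted over the list alone, 6 and 1 after centring). Among the targets the anthocyanin regulator MYB75 (2.01, SE 0.26) and SPL4 (1.25, SE 0.23) rose. In total limma called 281 genes higher and 1277 lower, 636 and 1053 after median centring, and 1050 and 573 with nuclear genes rescaled to a common total (1009 and 552 with the same genes tested). Without replicate 3 of wild type in NaCl, whose plastid share was 79.3%, 437 genes were called in all and the ROS list was not called (0.0677). Without its replicate 1 the counts were 656 higher and 3630 lower. CSD1 and PDF1.2A were not called after centring (0.0670 and 0.0916), nor were the miR172 target SNZ (−0.75, 0.102) and the root hair gene COBL9 (−0.33, 0.0836). CSD2 lost its call without replicate 1 of wild type on MS (0.0537), CDC20.1 without replicate 3 of wild type in NaCl (0.0584), and GOLS1, CSD1, AUR1, PDF1.2A, SPX1, SNZ and COBL9 when any 1 of 3 or more libraries was left out (up to 0.183, 0.209, 0.0981, 0.198, 0.101, 0.120 and 0.205).

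The same treatment in wild type changed 13 of 293 miRNAs, 8 upward and 5 downward (6 and 10 after centring, so the balance of directions depends on the scaling). The star strand miR169b-3p went from 2.22 ± 0.680 to 6.38 ± 0.813 RPM (SD, n = 3 each, log2 change 1.11, SE 0.16, limma adjusted p = 3.24e-05), and miR169f-3p (1.06, SE 0.25) and miR169g-3p (0.96, SE 0.22) rose with it. Copper-responsive miRNAs were called downward as a list (camera adjusted p = 4.25e-07, adjusted p = 0.363 with an estimated correlation), with 3 of 11 called, also when adjusted over the list alone. miR398c-5p fell from 3522 ± 147 to 2081 ± 63.1 RPM (−0.86, SE 0.11, 0.000153), and miR398b-5p (−0.79, SE 0.13) and miR408-5p (−0.66, SE 0.15) fell too. All 3 are 5p strands, and no 3p strand of the list was called. The 3 tested miR398 targets did not rise. Their median change was −0.75, and 2 of them, CSD1 and CSD2, were called lower as deposited. As the called miR398 strands were 5p strands alone, this is no test of miR398 acting on its targets. The phosphate and sulfate list was called upward (0.0406, 2 of 14 and 7 adjusted over the list alone, adjusted p = 0.652 with an estimated correlation). Within it miR395c, which targets sulfate assimilation genes, rose from 4.76 ± 0.883 to 9.37 ± 1.08 RPM (0.75, SE 0.16). miR3434-5p (0.58, SE 0.17, 0.0675 after centring), miR824-3p (−0.64, SE 0.15) and miR866-3p (−0.58, SE 0.13) were also called. Of 140 families, miR169 (0.99, SE 0.24), miR3434 (0.58, SE 0.17), miR395 (0.53, SE 0.14) and miR775 (0.48, SE 0.13) rose and miR398 (−0.64, SE 0.12) fell. With the replicate number as a block 9 families were called against these 5 (6 higher and 3 lower), and after centring 4 higher and 5 lower. The conserved, young and siRNA trigger lists were not called (0.657, 0.657 and 0.136). They had 8 higher and 3 lower, 1 higher, and 4 higher adjusted over the list alone. No family call was left without replicate 1 or without replicate 3 of wild type in NaCl (0 called in each case), and the miRNA count was 6 without replicate 1 of wild type on MS. Without that library miR169f-3p and miR169g-3p lost their calls (0.0629), and miR3434-5p, miR408-5p, miR824-3p and miR866-3p did when any 1 of 4 or more libraries was left out (up to 0.141, 0.199, 0.199 and 0.126).

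The next comparison asked the same of the mutant. In sos2-2, 18 of 22 ABA and dehydration genes rose and 0 fell (19 adjusted over the list alone, camera adjusted p = 1.43e-25, adjusted p = 0.00425 with an estimated correlation). COR15A went from 7.36 ± 7.53 to 187 ± 42.7 TPM (SD, n = 2 and 3, log2 change 4.68, SE 0.41, limma adjusted p = 6.79e-07) and KIN1 from 12.1 ± 6.57 to 287 ± 66.7 TPM (4.37, SE 0.31). LTP4 (5.60, SE 0.27), LTP3 (4.98, SE 0.33) and AT2G37870 (4.97, SE 0.40) had the largest rises, and NRT2.1 went from 1.2997 ± 0.0598 to 30.8 ± 4.93 TPM (3.62, SE 0.24, 2.79e-08). Osmolyte genes were called upward (0.000154, 0.257 with an estimated correlation, 4 of 8 higher, also when adjusted over the list alone), led by P5CS1 (2.41, SE 0.21) and the raffinose synthase gene RS5 (0.83, SE 0.21). Jasmonate genes were called upward (0.00556, 0.371 with an estimated correlation, 5 of 11 higher and 1 lower, 6 and 1 adjusted over the list alone, 4 and 1 after centring), with VSP2 (2.45, SE 0.35) and LOX2 (1.55, SE 0.26) rising and PDF1.2A (−2.57, SE 0.41) falling.

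Cell cycle genes were called downward in sos2-2 (1.55e-06, 0.267 with an estimated correlation, 2 of 9 lower, 4 adjusted over the list alone and 8 after centring), with CDC20.1 at −0.95 (SE 0.23, 0.0452) and CYCB1;2 at −0.89 (SE 0.22, 0.0498). The alternative oxidase gene AOX1A rose from 3.20 ± 0.900 to 23.48 ± 5.18 TPM (SD, n = 2 and 3, 2.37, SE 0.27, 6.92e-06) and the stress zinc-finger gene ZAT12 from 3.13 ± 1.12 to 13.6 ± 4.07 TPM (1.64, SE 0.25). The ROS list was not called (0.329, 3 of 16 higher and 5 adjusted over the list alone, 3 higher and 1 lower after centring). The phosphate transporter gene PHT1;1 rose from 12.3 ± 1.15 to 40.3 ± 6.93 TPM (1.47, SE 0.24). Among miRNA targets MYB75 (2.49, SE 0.29) and the laccase gene LAC12 (1.70, SE 0.20) rose. The largest falls were those of AT3G46880 (−2.86, SE 0.26), PDF1.2A, AT3G15356 (−2.56, SE 0.36), AT3G16530 (−2.53, SE 0.34), the glycine-rich protein gene DOT1 (−2.42, SE 0.54, 0.0570 after centring) and PCC1 (−2.38, SE 0.42). Photosynthesis genes had 0 of 21 called, also when adjusted over the list alone, and 3 lower after centring. The list passed camera downward at 0.0325 (0.0569 after centring, 0.824 with an estimated correlation, 0.139 with the replicate number as a block, 0.344 without replicate 1 of sos2-2 in NaCl, and 0.790 in the other direction without replicate 2 of sos2-2 on MS). Not called were the lists of SOS and ion transport (0.508, NHX2 at 0.48, SE 0.19, as 1 of 15 higher, also adjusted over the list alone, 0 after centring) and small RNA machinery (0.536, 0 of 24). Root markers (0.229, 3 of 10 higher adjusted over the list alone, 1 after centring), phosphate starvation (0.956, 1 higher and 1 lower of 7 adjusted over the list alone) and miRNA targets (0.198, 3 of 66 higher, also adjusted over the list alone, 3 higher and 1 lower after centring) were not called either. limma called 937 genes higher and 155 lower in all, and 764 and 697 after median centring. The total was 449 without replicate 2 of sos2-2 on MS or 651 without replicate 1. Without replicate 1 the jasmonate list was not called either (0.0740), and without replicate 2 RS5 was not (0.0757). DOT1, NHX2, CDC20.1 and CYCB1;2 lost their calls when any 1 of 4 or more libraries was left out (up to 0.169, 0.252, 0.252 and 0.236).

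In sos2-2 salt changed 11 miRNAs, 5 upward and 6 downward (22 and 15 after centring). All 14 tested phosphate and sulfate miRNAs lay above the median miRNA (3 called, 10 adjusted over the list alone, camera adjusted p = 2.55e-11, adjusted p = 0.0346 with an estimated correlation). miR395f went from 5.54 ± 0.289 to 10.3 ± 3.01 RPM (SD, n = 3 each, log2 change 0.79, SE 0.18, limma adjusted p = 0.0203), and miR395c (0.76, SE 0.16) and miR395d (0.60, SE 0.16) rose too. Members of a family, such as these or miR398b-5p and miR398c-5p, can count the same reads. The 14 miRNAs of this list, here and below, may therefore be fewer than 14 separate signals. miR169b-3p rose from 1.96 ± 0.261 to 4.37 ± 0.0427 RPM (0.90, SE 0.16, 0.00253) and miR3434-5p by 0.69 (SE 0.17). miR824-3p, from MIR824 on chromosome 4 (12625094 to 12625782), fell from 277 ± 16.1 to 151 ± 20.8 RPM (−0.84, SE 0.15, 0.00207). miR156d-3p (−0.61, SE 0.16), miR164c-3p (−0.60, SE 0.17), miR398b-5p (−0.57, SE 0.13) and miR398c-5p (−0.51, SE 0.11) fell. By family, miR395 (0.67, SE 0.14), miR3434 (0.64, SE 0.17), miR827 (0.55, SE 0.15) and miR775 (0.46, SE 0.13) rose, and miR824 (−0.77, SE 0.15), miR5633 (−0.57, SE 0.16), miR398 (−0.47, SE 0.12), miR8165 (−0.44, SE 0.13) and miR866 (−0.42, SE 0.12) fell. The copper, siRNA trigger, conserved and young lists were not called (0.218, 0.241, 0.598 and 0.598, with 1 higher and 3 lower, 0, 10 higher and 8 lower, and 1 lower adjusted over the list alone). After median centring 9 families were higher and 4 lower, with miR5633 and miR8165 no longer among them (0.0538 and 0.0727), and without replicate 3 of sos2-2 in NaCl 2 miRNAs and 1 family were called. Of the named miRNAs only miR169b-3p and miR824-3p were called without each library in turn (others up to 0.198).

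**Figure D2:**
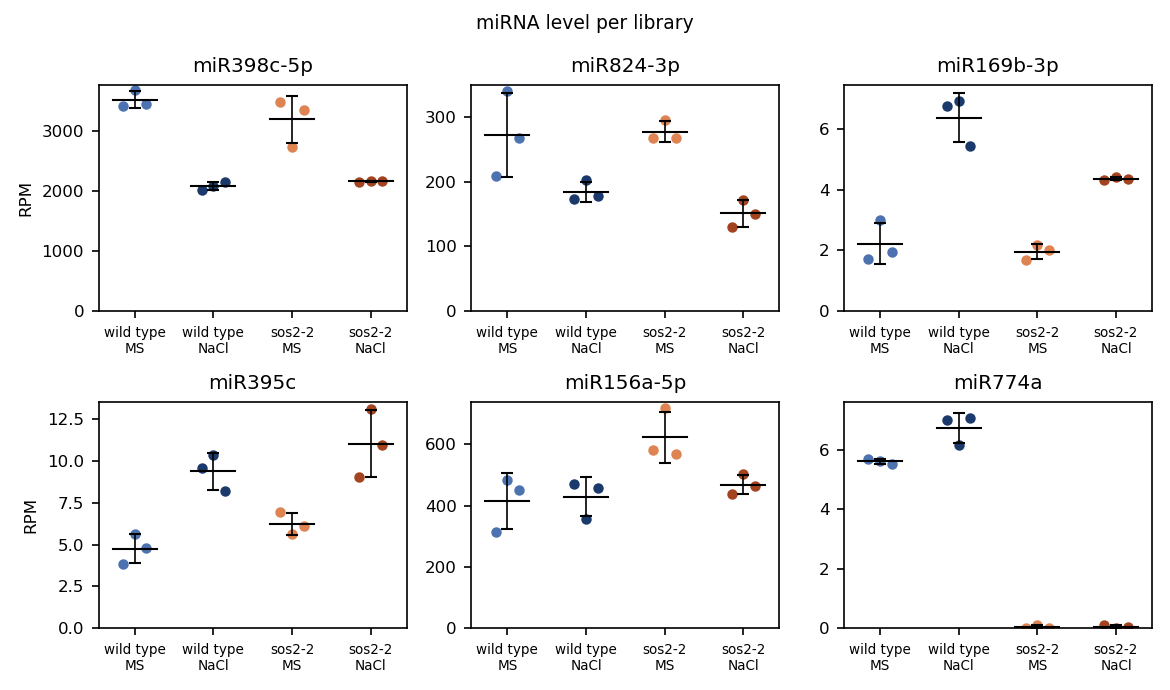
RPM of 6 mature miRNAs in each small RNA library, by genotype and medium, on linear axes that start at 0. Points are libraries, long bars group means and whiskers SD (n = 3). miR398c-5p is lower in NaCl in both genotypes, and miR774a is near 0 in the 6 sos2-2 libraries and at 5.53 RPM or more in the 6 wild-type libraries.

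The third comparison set sos2-2 against wild type on MS. Apart from ATMG00210, which is uncertain as given below, the largest rises were in the glycine-rich RNA-binding protein gene CCR1, from 9.86 ± 5.22 to 146 ± 16.1 TPM (SD, n = 3 and 2, log2 change 3.95, SE 0.71, limma adjusted p = 0.0126), DOT1 (3.57, SE 0.54), AT1G58983 (3.18, SE 0.61), AT1G80130 (3.02, SE 0.65) and the glycine-rich protein gene GRP-3 (2.90, SE 0.57). UBC1, a ubiquitin-conjugating enzyme gene, fell from 46.7 ± 0.736 to 14.8 ± 0.604 TPM (−1.54, SE 0.23, 0.00446). Also lower were NOXY2 (−1.73, SE 0.28), the cystine lyase gene CORI3 (−1.69, SE 0.29), TOM7-2 (−1.62, SE 0.31), the histone gene HTA4 (−1.57, SE 0.23) and AT3G26510 (−1.56, SE 0.34). ATMG00210, a mitochondrial ribosomal protein L5 gene, was listed at 0 in the 6 wild-type libraries and at 13.8 to 95.9 TPM in the 5 sos2-2 libraries. A nuclear copy, AT2G07725 on chromosome 2, had all of its 697 windows of 50 bases in the mitochondrial genome and was at 135 to 194 TPM in wild type and 222 to 348 TPM in sos2-2. Reads can move between the copies and the change of either is uncertain.

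Photosynthesis genes were lower in sos2-2 on MS as a list (camera adjusted p = 0.000998, adjusted p = 0.817 with an estimated correlation, 2 of 21 called and 5 adjusted over the list alone). The call was lost without replicate 1 of sos2-2 on MS (0.392) and with the purine trend as a covariate (0.106). LHCB4.1, of the light-harvesting antenna, was at 1319 ± 174 TPM in wild type and 451 ± 26.7 in sos2-2 (SD, n = 3 and 2, −1.48, SE 0.26, 0.00942) and RBCS1A changed by −1.16 (SE 0.31). Known miRNA targets were lower too (0.00612, 0.817 with an estimated correlation, 2 of 66 called, 7 lower and 1 higher adjusted over the list alone, 14 and 1 after centring). This call was lost when each library's purine and length trend was removed (0.177) and with the covariate (0.0981). The list was led by the leaf growth regulators TCP3 (−1.27, SE 0.34) and TCP4 (−1.22, SE 0.28), which are miR319 targets. Single members of other lists fell: NRT2.1 (−1.22, SE 0.24), COR15A (−1.51, SE 0.41, 0.0691 after centring), the vacuolar exchanger gene NHX1 (−0.87, SE 0.23) and HESO1 (−0.95, SE 0.26, 0.0499), whose product adds uridines to unmethylated small RNAs. The lists themselves were not called: ABA and dehydration 0.754 (1 of 22 adjusted over the list alone), SOS and ion transport 0.754 (1 of 15), osmolytes 0.392 (1 of 8), and ROS 0.104 (0 of 16, 2 lower after centring). Nor were small RNA machinery 0.754 (1 higher and 1 lower of 24, 0 and 1 after centring), root markers 0.104 (4 of 10 lower), cell cycle 0.104 (2 of 9 lower), jasmonate 0.104 (3 of 11 lower, 2 after centring) and phosphate starvation 0.754 (0 of 7). With the covariate ABA and dehydration was called downward (0.0282). Of all genes, 258 were called higher and 204 lower, 635 and 1070 after centring, 873 and 559 with nuclear genes rescaled, and 967 and 626 with the same genes tested, so the balance of directions is not settled. The total was 10 or 6 without replicate 1 or 2 of sos2-2 on MS, and 60 higher and 11 lower were called with the library purine trend as a covariate. With that covariate DOT1, CORI3, HTA4, UBC1 and HESO1 were still called. CCR1 (1.82, 0.0775), AT1G58983, AT1G80130, GRP-3, NOXY2, TOM7-2, AT3G26510, LHCB4.1, RBCS1A, TCP3, TCP4, NRT2.1, COR15A and NHX1 were not called with it. Without replicate 1 of sos2-2 on MS each of these 19 genes lost its call, and without replicate 2 each but COR15A did (adjusted p up to 0.4602 over the left-out libraries). The change of COR15A, −1.57 as deposited, was −0.479 without replicate 1 and −2.65 without replicate 2 of sos2-2 on MS, so its size is uncertain.

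Among small RNAs on MS, miR774a was nearly absent from the mutant. It was at 5.53 to 7.08 RPM in the 6 wild-type libraries of both media (94 to 139 reads each) and at 0 to 0.115 RPM in the 6 sos2-2 libraries (0 to 2 reads each). The miR774 family was called lower on MS (log2 change −2.67, SE 0.13, limma adjusted p = 6.34e-12) and in NaCl (−2.74, SE 0.13, 1.70e-12). MIR774a lies on chromosome 1 (22149936 to 22150033), between MIR859 (22149718 to 22149843) and MIR774b (22150128 to 22150266). The miR843 family, from MIR843 on chromosome 3 (17742098 to 17742302), was at 0.900 ± 0.269 RPM in wild type and 2.86 ± 1.09 in sos2-2 on MS (SD, n = 3 each, 0.999, SE 0.20, 0.00636) and was called higher in NaCl too (1.17, SE 0.20, 0.00390). miR156a-5p, which targets SPL transcription factor genes, rose from 416 ± 90.9 to 623 ± 83.0 RPM (0.59, SE 0.15, 0.0333). miR156f-5p (0.61, SE 0.16), miR156g (0.60, SE 0.17), miR156c-5p (0.58, SE 0.15) and miR164c-3p (0.82, SE 0.17) rose with it. In wild type on MS miR156a-5p, miR156c-5p and miR156f-5p had near-equal means of 416, 420 and 406 RPM. They can count the same reads, so their calls may be 1 signal. Summed as a family, miR156 was not called on MS (0.45, limma adjusted p = 0.103). In all 11 miRNAs were called higher and 2 lower (15 and 6 after centring), and 1 family each way (2 higher and 4 lower after centring). Conserved families were called upward and young families, the rest of the miRNAs, downward (camera adjusted p = 0.00288 for both, adjusted p = 0.847 and 0.768 with an estimated correlation, 9 higher and 1 lower, and 1 higher and 2 lower, adjusted over the list alone). As the 2 lists together hold every tested miRNA, this is 1 result and not 2. Phosphate and sulfate miRNAs were called upward (0.0143, 0.768 with an estimated correlation, 1 of 14 adjusted over the list alone). The copper and siRNA trigger lists were not called (0.541 and 0.907, 0 adjusted over the list alone). The miRNA count was 2 without replicate 1 of wild type on MS, and the miR156 calls were also lost without replicate 2 or 3 of sos2-2 on MS (highest adjusted p = 0.180). The change of miR156g, 0.61 as deposited, was 0.39 without replicate 1 of wild type on MS. The miR843 call on MS was lost without replicate 1 of wild type or replicate 3 of sos2-2 on MS (up to 0.0517).

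The fourth comparison set the genotypes against each other in NaCl. GSTU9, a glutathione S-transferase gene, was at 1.202 ± 0.645 TPM in wild type and 28.4 ± 11.6 in sos2-2 (SD, n = 3 each, log2 change 3.37, SE 0.27, limma adjusted p = 2.82e-07). Among called genes with a mean log2 value of at least 2, AT2G18193 (3.35, SE 0.32), AT4G12495 (3.19, SE 0.63), AT5G13210 (3.18, SE 0.30) and AT5G48430 (2.87, SE 0.20) were the next largest rises apart from ATMG00210, whose copies are described above. AOX1A was at 3.75 ± 1.77 TPM in wild type and 23.48 ± 5.18 in sos2-2 (2.09, SE 0.24, 2.63e-06) and ZAT12 at 1.90 ± 0.563 and 13.6 ± 4.07 TPM (1.99, SE 0.22). PHT1;1 (1.002, SE 0.21), the senescence regulator ORE1 (1.103, SE 0.25), a miR164 target, LEA4-5 (0.86, SE 0.19) and PRODH1 (0.64, SE 0.22) were higher as well. Lower in sos2-2 were AT4G08400 (−1.83, SE 0.32), GSTF14 (−1.79, SE 0.26), CORI3 (765 ± 120 against 310 ± 108 TPM, −1.67, SE 0.26), AT5G06630 (−1.56, SE 0.35), AT5G37990 (−1.55, SE 0.25), AT4G38080 (−1.48, SE 0.32), VSP1 (−1.23, SE 0.24), HESO1 (−1.03, SE 0.24) and the miR166 target ATHB8 (−0.90, SE 0.19). List members called higher as deposited but not after centring were LHCB2.1 (0.93), LHCB2.2 (0.85), DREB2A (0.82), NRT2.1 (0.57), NLA (0.55), KUP6 (0.53), SPX1 (0.48), JAZ1 (0.44), EXPA18 (0.43), RS5 (0.38) and CAX3 (0.38). VSP1 lost its call without replicate 1 of sos2-2 in NaCl (0.0595), and AT5G06630, AT4G38080, HESO1 and ATHB8 when any 1 of 3 or more libraries was left out (up to 0.120, 0.105, 0.161 and 0.138). The change of AT4G38080, −1.16 as deposited, was −0.775 without replicate 2 of wild type in NaCl.

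As lists, cell cycle genes lay lower in sos2-2 in NaCl (camera adjusted p = 0.000437, adjusted p = 0.863 with an estimated correlation, 0 of 9 called, 0 adjusted over the list alone, and after centring 4 lower, 8 adjusted over the list alone). So did known miRNA targets (0.00808, 0.863 with an estimated correlation). Of these 7 of 66 were called higher and 1 lower as deposited (4 and 0 adjusted over the list alone) and 1 higher and 13 lower after centring (1 and 15). The call of the targets was lost without replicate 1 of wild type or of sos2-2 in NaCl (up to 0.0868). The other lists were not called, and their counts adjusted over the list alone differed with centring. ABA and dehydration (0.559) had 7 of 22 higher as deposited and 1 higher and 1 lower after centring, SOS and ion transport (0.463) 4 of 15 higher and then 1 higher and 4 lower, osmolytes (0.463) 2 of 8 and then 1 higher, and ROS (0.230) 6 of 16 higher and then 4 higher and 1 lower. Photosynthesis (0.524) went from 7 higher and 1 lower of 21 to 0 and 1, root markers (0.826) from 4 of 10 higher to 2 higher and 3 lower, jasmonate (0.0590) from 1 higher and 1 lower of 11 to 0 and 2, and phosphate starvation (0.524) from 2 of 7 to 1 higher. Small RNA machinery (0.0590, and downward at 0.0479 after centring) went from 0 of 24 to 4 lower. limma called 3138 genes higher and 67 lower. The counts were 821 and 936 after median centring and 1205 and 581 with nuclear genes rescaled to a common total. Plastid transcripts took 75.0% of the TPM in wild type and 67.9% in sos2-2 here. The total was 1128 without replicate 3 and 5569 without replicate 1 of wild type in NaCl.

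In NaCl 5 miRNAs were higher and 5 lower in sos2-2, but 14 and 4 after centring and 13 and 4 with DESeq2, so the even split depends on the scaling. All 14 phosphate and sulfate miRNAs lay above the median miRNA (1 called, 7 adjusted over the list alone, camera adjusted p = 6.15e-14, adjusted p = 0.0179 with an estimated correlation). Among them miR395d was at 7.42 ± 0.881 RPM in wild type and 11.8 ± 0.872 in sos2-2 (SD, n = 3 each, log2 change 0.74, SE 0.16, limma adjusted p = 0.0304). The copper list was called upward (0.0243, 1 of 11, also adjusted over the list alone, adjusted p = 0.647 with an estimated correlation), with miR398a-5p at 0.79 (SE 0.17). miR8175 (0.85, SE 0.15) and miR845a (0.82, SE 0.19) were also higher and miR863-5p (−0.44, SE 0.13) and miR3932b-5p (−0.41, SE 0.14) lower. Of the families, miR845 (0.83, SE 0.20), miR8175 (0.86, SE 0.14), miR2111 (0.75, SE 0.17) and miR859 (0.66, SE 0.15) were higher besides miR843. Lower besides miR774 were miR5020 (−0.65, SE 0.17), miR3932 (−0.41, SE 0.13), miR870 (−0.40, SE 0.14), miR863 (−0.38, SE 0.12), miR5645 (−0.34, SE 0.14) and miR8121 (−0.31, SE 0.13). The change of miR859, 0.52 as deposited, was 0.33 and not called without replicate 2 of wild type in NaCl (adjusted p = 0.167). The calls of miR5645, miR8121 and miR870 were lost after centring (0.117, 0.168 and 0.178), which left 7 families higher and 4 lower. Conserved families were again called upward and young ones downward (0.00251 each, 0.647 with an estimated correlation, 0 and 4 higher and 6 lower adjusted over the list alone), and the siRNA triggers were not called (0.782, 0 adjusted over the list alone). As deposited 42 of 128 conserved miRNAs were higher in sos2-2, so upward is relative to the other miRNAs. The miRNA count was 2 without replicate 3 of sos2-2 in NaCl. Each of the 6 named miRNAs lost its call without replicate 3 of either group in NaCl (adjusted p up to 0.252).

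The last comparison asked which genes responded to salt differently in the 2 genotypes. Across the 16564 genes, which are not independent, the salt responses correlated with Pearson's r = 0.352 and Spearman's rho = 0.265, and no library was shared between them. Of the calls, 178 rises were common to both genotypes against 15.9 expected of independent lists, and 96 falls against 11.9 expected (283 against 29.3 and 269 against 44.3 after centring), while 12 genes were called in opposite directions (8 after centring). A positive interaction is a salt change more positive in sos2-2, which can be a larger rise or a smaller fall. That of GSTU9 was 3.36 (SE 0.41, limma adjusted p = 6.97e-05). Its level went from 2.55 ± 0.435 to 1.202 ± 0.645 TPM in wild type and from 2.41 ± 0.481 to 28.4 ± 11.6 TPM in sos2-2 (SD, n = 3, 3, 2 and 3). Among called genes with a mean log2 value of at least 2, AT5G48430 (3.10, SE 0.30), BCS1 (3.02, SE 0.46), which encodes a mitochondrial AAA protein, the sulfotransferase gene SOT12 (3.00, SE 0.41), AT2G01379 (2.98, SE 0.74, 0.187 after centring) and AT4G08555 (2.88, SE 0.45) came next. AT2G01379 fell in wild type and was not called in sos2-2 (−0.30). BCS1 was at 4.22 ± 0.901 and 3.13 ± 0.305 TPM in wild type and at 3.11 ± 1.68 and 35.7 ± 16.9 TPM in sos2-2.

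The ROS list had a positive interaction (camera adjusted p = 0.00221, adjusted p = 0.906 with an estimated correlation, 3 of 16 called, 7 adjusted over the list alone and 4 after centring). Its median salt change was −0.27 in wild type and −0.02 in sos2-2, where the list was not called. AOX1A (interaction 1.85, SE 0.36) and ZAT12 (1.37, SE 0.33) rose in sos2-2. The photosynthesis list had a positive interaction as a smaller decrease in sos2-2, with medians of −0.64 in wild type and −0.12 in sos2-2 (0.000161, 0.906 with an estimated correlation, 0 of 21 called, 15 adjusted over the list alone and 0 after centring). Set against wild type, the median of this list in sos2-2 was −0.36 on MS and 0.10 in NaCl. Its interaction thus also holds the lower level on MS, which rests on 2 sos2-2 libraries. NRT2.1 (1.77, SE 0.32), PRODH1 (1.37, SE 0.32), DREB2A (1.37, SE 0.31), PHT1;1 (1.23, SE 0.32), the jasmonate repressor gene JAZ1 (1.13, SE 0.32) and LEA4-5 (0.99, SE 0.28) had positive interactions within lists that were not called. These lists were root markers 0.201 (1 of 10 adjusted over the list alone), osmolytes 0.215 (2 of 8, 1 after centring), ABA and dehydration 0.602 (4 of 22, 0 after centring, and 0.0450 with the trend removed or 0.00120 with the covariate), phosphate starvation 0.602 (2 of 7, 1 after centring) and jasmonate 0.912 (1 of 11). PRODH1 fell in wild type and was not called in sos2-2 (0.19). SOS and ion transport (0.769), small RNA machinery (0.0648), cell cycle (0.403) and miRNA targets (0.638) had 0 members called, also adjusted over the list alone. Negative interactions were called for DOT1 (−3.78, SE 0.73), AT5G05250 (−2.84, SE 0.56), AT2G07626 (−2.33, SE 0.35), GSTF14 (−2.08, SE 0.39), ATMG00970 (−1.98, SE 0.28) and AT2G43535 (−1.60, SE 0.30). ATMG00970 rose in wild type (1.1003) and was not called in sos2-2, and the others were called lower in sos2-2 and not called in wild type, where DOT1 was at 1.34. On MS DOT1 was already called higher and NRT2.1 lower in sos2-2, so their interactions also hold that difference. limma called 326 positive and 12 negative interactions, and 113 and 11 after centring. After centring DREB2A, LEA4-5, DOT1 and AT5G05250 were not called (0.192, 0.220, 0.141 and 0.156). With the library purine trend as a covariate AT5G05250, GSTF14, AT2G43535, LEA4-5, JAZ1 and PHT1;1 were not called (0.176, 0.113, 0.279, 0.0529, 0.0829 and 0.0527). The total was 128 without replicate 2 of sos2-2 on MS, when ZAT12, PHT1;1, JAZ1 and GSTF14 also lost their calls (adjusted p up to 0.0947, 0.0857, 0.153 and 0.230 over the left-out libraries). AT2G01379, DOT1, AT5G05250, AT2G43535 and LEA4-5 lost theirs without it too (up to 0.178, 0.124, 0.191, 0.253 and 0.0621). The total was 3545 without replicate 1 of wild type in NaCl. The photosynthesis call was lost without replicate 1 of sos2-2 on MS (0.220).

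No miRNA and no family was called in the interaction by limma (0 of 293 and 0 of 140, with 18 and 11 at an unadjusted p under 0.05). On the recovered reads edgeR called 0 and DESeq2 called 2 miRNAs. As lists, copper miRNAs (camera adjusted p = 0.00136, 11 of 11 above the median miRNA, 1 called adjusted over the list alone) and phosphate and sulfate miRNAs (6.15e-08, 14 of 14 above, 0 adjusted over the list alone) responded more positively in sos2-2, relative to the median miRNA. As deposited, 6 of 11 copper and 11 of 14 phosphate and sulfate miRNAs had a positive interaction. Adjusted p was 0.562 and 0.0942 with an estimated correlation. The conserved, young and siRNA trigger lists were not called (0.903 each, 0 adjusted over the list alone). The salt responses of miRNAs correlated between genotypes with r = 0.634 and rho = 0.562 across 293 miRNAs. Over 25 families with tested targets, no relation between the change of a family and the median change of its targets passed a permutation test in the 5 comparisons. Spearman's rho was 0.01, 0.08, −0.06, 0.07 and 0.22 (permutation adjusted p at least 0.951), and Pearson's r 0.01, −0.05, −0.09, 0.30 and 0.09. Family sums hold both strands of a miRNA, star strands included. These values therefore do not test the strands that act on the targets by themselves.

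**Figure D3:**
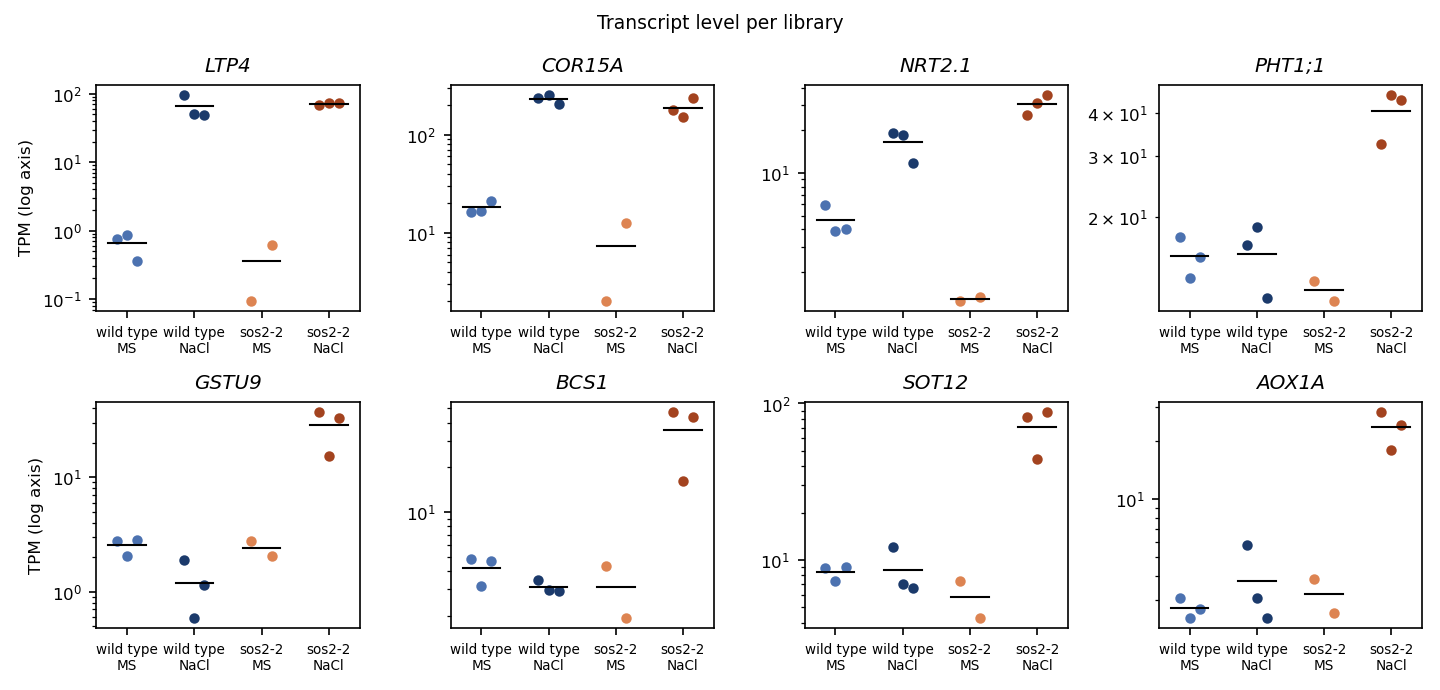
TPM of 8 genes in each mRNA library on log axes, by genotype and medium, with bars at group means. LTP4 and COR15A are higher in NaCl in both genotypes, whereas GSTU9, BCS1, SOT12 and AOX1A reach their highest levels in the 3 sos2-2 libraries in NaCl.

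**Figure D4:**
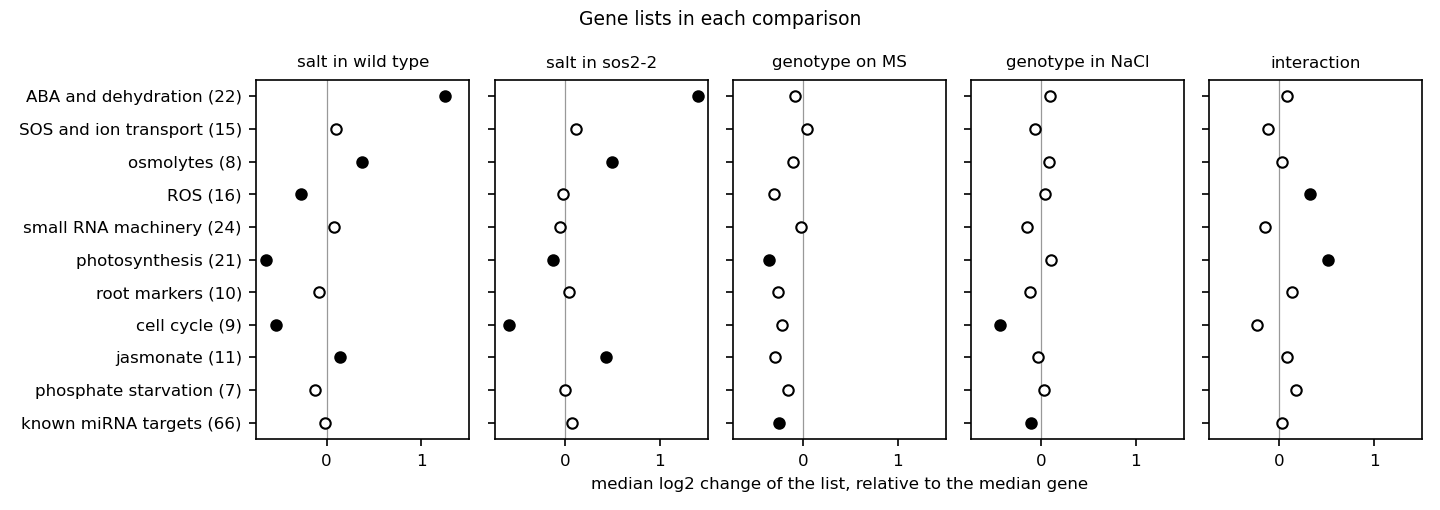
Median log2 change of each gene list relative to the median gene in the 5 comparisons, with the number of tested genes in brackets. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and the ABA and dehydration list has the largest medians, 1.25 for salt in wild type and 1.40 for salt in sos2-2.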

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

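Both tests of the plastid share, the covariate test on MS and the test for mislabelled libraries were chosen after their results were seen, and the tests on miR774b reads, on neighbouring genes, on linkage, on the purine trend in the interaction and on other splits before. Before means before the result of that test was seen. The removal of the purine trend was itself added after the data were seen.

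The salt responses of the genotypes differed, by the limma interaction on the values as deposited, in 338 genes. After median centring 113 of the 326 positive and 5 of the 12 negative calls were kept. Salt changes more positive in sos2-2 included those of GSTU9 (3.36), AT5G48430 (3.10), BCS1 (3.02), SOT12 (3.00), AT2G01379 (2.98), AT4G08555 (2.88), AOX1A (1.85), NRT2.1 (1.77), PRODH1 (1.37), ZAT12 (1.37), DREB2A (1.37), PHT1;1 (1.23), JAZ1 (1.13) and LEA4-5 (0.99). More negative ones were those of DOT1 (−3.78), AT5G05250 (−2.84), AT2G07626 (−2.33), GSTF14 (−2.08), ATMG00970 (−1.98) and AT2G43535 (−1.60). Of these genes AT2G01379, DREB2A, LEA4-5, DOT1 and AT5G05250 were not called after centring. The difference was also called for the ROS list (adjusted p = 0.00221), the photosynthesis list (0.000161), the copper miRNAs (0.00136) and the phosphate and sulfate miRNAs (6.15e-08), and adjusted p was 0.906, 0.906, 0.562 and 0.0942 for these with an estimated correlation. The list calls are relative to other genes or miRNAs, and as deposited 6 of 11 copper miRNAs had a positive interaction. Photosynthesis genes were already lower as a list in sos2-2 on MS.

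The first pattern is the lopsided direction of the calls. In NaCl 97.9% of the genotype calls were rises in sos2-2, and with nuclear genes rescaled to a common total and filtered again (19686 tested) 67.5% were. With the 16369 tested nuclear genes kept and only their library totals made equal the share was 65.1%. Any scaling that lowers all nuclear genes alike lowers it (46.7% after centring), so the drop does not single out the plastid share. Nuclear totals differed by a log2 value of 0.37 and the median gene by 0.32, so the makeup of the libraries is large enough for much of the excess. For the interaction the share of positive values was 96.4% as deposited and 93.7% and 92.9% after the same rescalings, which argues against the plastid share as the whole cause of the direction. The first left 134 positive calls against 326, 117 of them the same genes, and moved the median interaction from 0.39 to −0.004, and the second left 130, all among the 326, so most of the calls were lost with that shift. Why the plastid share differed was not tested, and a difference between the genotypes stays open.

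The second pattern is the library trend with transcript purine share. The 326 positive interactions had a median of 1.17 (SD 0.61) and of 1.11 (SD 0.65) after each library's trend was removed, so 95.2% was kept, which argues against the trend as the whole source of their size. The removal was done with median centring, after which 113 of these genes were called without it and 109 with it, so most calls ended with the shift of the median gene. The median kept 96.1% with the trend as a covariate. The 258 rises in sos2-2 on MS went from a median of 1.26 (SD 0.59) to 0.68 (SD 0.48) with the covariate, so 54.0% was kept and 28 were still called, while removal per library with centring kept 90.1%, and 203 were still called (204 after centring alone). Since the trend differs between these groups, with 3 libraries below 0 and 2 above, a library effect and an effect of the genotype cannot be told apart for the rises on MS.

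The third pattern is the near absence of miR774a from sos2-2, with 5 reads over its 6 libraries against 673 in wild type. miR774b differed by −0.0369 RPM between the genotypes while miR774a lost 6.14 RPM, which argues against reads counted for the other copy. The 8 tested genes within 50 kb had median log2 changes of 0.24 on MS and 0.04 in NaCl (lower median 0.0406, range −0.23 to 0.67), which argues against a deletion that takes in these genes. That all 6 sos2-2 libraries lay under every wild-type library is the pattern itself, so it does not test mislabelled libraries. A sequence variant of the mutant line at the locus and an effect of the mutation stay open, as untested.

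The 6 libraries of a comparison make 10 splits, the real one included, which cannot give a share under 0.05. The real count and the highest of the other splits, with 1 of 10 splits as large in each case, were 1558 and 0 genes for salt in wild type and 3205 and 175 for genotype in NaCl. For miRNAs they were 13 and 0 for salt in wild type, 11 and 0 for salt in sos2-2, 13 and 2 for genotype on MS and 10 and 0 for genotype in NaCl. For families they were 5 and 0, 9 and 0, 2 and 1, and 12 and 0 in the same order. For salt in wild type, the splits of small RNA libraries ignored the pairing by replicate number that was taken for that comparison. In the interaction limma called 0 miRNAs and 0 families, so all 100 drawn splits were as large, with a highest of 8 in each.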

How the results depend on the processing

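The tests with nuclear genes rescaled, purine trends removed or as a covariate, edgeR and DESeq2 were chosen after seeing the data. Over 31 results 418 values were compared, of which 272 stayed within 1.5 times or within their spread and 146 did not. Of 2974 leave-one-out values for 265 named results 2515 kept their side of the threshold, 426 lost a call, 32 gained one and 1 reversed. Median centring kept 227 of 265 named results (30 lost, 8 gained), quantile normalization 143 of 182, no filter 122 of 182, a pseudocount of 0.1 174 of 182, and only the libraries compared 143 of 155. Both rescalings kept 122 of 148, trend removal lost 21 calls and gained 9 of 203, and the covariate kept 175 of 206. edgeR with library totals and DESeq2 kept 31 of 31 named miRNA results each and edgeR with TMM 30 of 31. The cause of the changes below was not tested, except that a fold filter leaves fewer calls by construction. DESeq2 on mRNA was not run, since TPM are not counts, and where 1 library of sos2-2 on MS was left it was assumed to vary as the other groups do. Without a known mRNA depth, the precision of low genes cannot be stated.

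Main counts were 1558, 1092, 462, 3205 and 338 genes and 13, 11, 13, 10 and 0 miRNAs for salt in wild type, salt in sos2-2, genotype on MS, genotype in NaCl and the interaction. No filter gave 862 genes for salt in wild type and 12 for genotype on MS, and 6, 3 and 7 miRNAs in the first 3 comparisons. A fold change of at least 2 gave 477, 622, 307 and 670 genes and 3, 0, 1 and 2 miRNAs in the first 4. Single transcripts gave 689, 628, 120 and, for the interaction, 128. Quantile normalization gave 1583, 1751 and 155 genes in the last 3, and 37 miRNAs for salt in sos2-2 and 19 for genotype in NaCl. Median centring gave 1705, 1757 and 124 genes in the last 3, 37, 21 and 18 miRNAs for salt in sos2-2 and the genotypes, and 9 families against 5 for salt in wild type and 6 against 2 for genotype on MS. Only the libraries compared gave 1903 genes for genotype on MS, 26 miRNAs for salt in sos2-2 and 3 for genotype on MS. Family sums gave 5 for salt in wild type and 2 for genotype on MS.

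Rescaled nuclear genes gave 1432, 1786 and 143 in the last 3 comparisons, and 1593, 1684 and 140 with the same genes tested. Trend removal gave 1660, 1789, 1996 and 124 in the last 4, 1 called gene list against 2 for genotype on MS, and r = 0.436 against 0.352 between the salt responses. The covariate gave 642 for salt in wild type, 71 for genotype on MS and 199 for the interaction, and for genotype on MS 1 gene list, ABA and dehydration, in place of the 2. DESeq2 gave 21, 43, 23, 17 and 2 miRNAs, and edgeR with TMM 45 for salt in sos2-2 and 24 for genotype on MS. With an estimated correlation 1, 1, 0, 0 and 0 gene lists were called against 6, 5, 2, 2 and 2, and 0, 0, 1 and 0 miRNA lists against 2, 3, 4 and 2, salt in sos2-2 left out. For the genotypes the conserved and young lists count as 2 of these miRNA lists but are 1 result. fry, which tests a list against no change and not against other genes, called 3 gene lists for salt in wild type, 0 and 4 for the genotypes and 5 for the interaction. The known miRNA targets had the other sign with fry for genotype in NaCl (adjusted p = 0.336), where the median gene was 0.32 higher, which is no reversal against other genes. Photosynthesis reversed for salt in sos2-2 without replicate 2 of sos2-2 on MS (0.790, lowest leave-one-out value 5.22e-06 without its replicate 1).

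The deviations of same-numbered libraries correlated above r = 0.1 in 7 of 15 pairs for mRNA (r from −0.526 to 0.294, 9 of 30 differently numbered pairs) and in 10 of 18 for small RNA (−0.128 to 0.377, mean 0.133, against 1 of 36 and a mean of −0.067). Deviations from a group mean cancel within the group, so the lower mean of differently numbered pairs follows from that of same-numbered ones. It is no separate baseline. All 3 pairs passed only for small RNA of wild type on MS and in NaCl, where the block changed no call of a named miRNA or family. Elsewhere the numbers were not taken to pair the libraries, though an effect shared by number is not excluded for small RNA. The replicate block gave 1753, 1082, 340, 3438 and 437 genes, 25 miRNAs for salt in sos2-2, 17 for genotype in NaCl and 9 families for salt in wild type, and kept 253 of 265 named results.

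Leaving out 1 library gave 437 (without replicate 3 of wild type in NaCl) to 4286 genes (without its replicate 1) for salt in wild type, 449 (replicate 2 of sos2-2 on MS) to 1459 (replicate 1 of wild type in NaCl, as for the next 3 highest) for salt in sos2-2, 6 (replicate 2 of sos2-2 on MS) to 1431 for genotype on MS, 1128 (replicate 3 of wild type in NaCl) to 5569 for genotype in NaCl, and 128 (replicate 2 of sos2-2 on MS) to 3545 for the interaction. For miRNAs it gave 6 to 17, 2 to 32, 2 to 16, 2 to 14 and 0 to 1, with the lowest values without replicate 1 of wild type on MS (salt in wild type, where leaving out replicate 1 of wild type in NaCl also gave 6, and genotype on MS) or replicate 3 of sos2-2 in NaCl (salt in sos2-2 and genotype in NaCl). For families it gave 0 to 8, 1 to 10, 1 to 7 and 5 to 15, with the lowest without replicate 1 or 3 of wild type in NaCl, replicate 3 of either sos2-2 group, replicate 3 of sos2-2 on MS, and replicate 2 of wild type or 3 of sos2-2 in NaCl. For gene lists it gave 1 (without replicate 1 of sos2-2 on MS) to 6 (without its replicate 2) for genotype on MS and 1 to 4, without the same libraries, for the interaction. The correlation of the salt responses was 0.225 to 0.449 (without replicates 1 and 3 of wild type in NaCl).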

Other observations

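The tests of mitochondrial stress genes and of detoxification families were chosen after seeing the interaction results, and the test of linkage before.

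Genes known to respond to mitochondrial stress had salt changes more positive in sos2-2. The list was drawn up from general knowledge after the interaction calls were seen, so it is not independent of them, and its values describe these genes without testing a cause. ABCB4, of an ABC transporter, was at 7.79 ± 0.627 TPM in wild type on MS, 8.61 ± 1.68 in wild type in NaCl, 10.5 ± 2.33 in sos2-2 on MS and 81.9 ± 30.1 in sos2-2 in NaCl (SD, n = 3, 3, 2 and 3, log2 difference of responses 2.29, SE 0.38, limma adjusted p = 0.000633). The glycosyltransferase gene UGT74E2 was at 1.51, 1.68, 2.06 and 20.497 TPM (2.28, SE 0.42, 0.00143), AT2G32020 at 0.909, 0.788, 0.740 and 25.3 TPM (3.36, SE 0.54, 0.000635), GSTU25 at 2.27, 3.66, 3.23 and 34.1 TPM (2.07, SE 0.39, 0.00148) and CRF6 at 2.08, 1.304, 2.098 and 9.03 TPM (1.77, SE 0.29, 0.000518). Of 16 tested genes of the list 11 were called (9 after centring), and 16 lay above the median gene, with a median of 1.92 and a range of 0.30 to 3.36. NAC13 (0.47, SE 0.36, 0.167) was not called. Called higher were 2 of the 16 for salt in wild type, 15 for salt in sos2-2, 0 for genotype on MS and 16 for genotype in NaCl. The median was 1.89 after removal of the library trends. Whether sos2-2 has a mitochondrial stress response in NaCl stays open.

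Families of detoxification and stress genes were picked after the interaction calls were seen and counted in the same calls, so their share describes the calls and tests nothing. Symbols of glutathione S-transferases, glycosyltransferases, cytochrome P450s, sulfotransferases, ABC transporters and WRKY factors were 39 of the called genes with a positive interaction and a symbol and 273 of 7359 other tested genes with one (odds ratio 7.84). After centring they made up 23 of 68 (odds ratio 12.7). By family, 13 of 44 WRKY, 6 of 39 GST, 5 of 41 UGT, 9 of 111 CYP and 5 of 75 ABC genes were called.

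Genes called in the same direction in both media after centring lay within 2 Mb of SOS2 in 7 of 491 cases, 1.41 times as often as 15878 other tested genes (Fisher's exact p = 0.357, 95% interval of the odds ratio 0.556 to 3.00). That interval leaves open whether variants linked to the mutation add to the differences. Between the genotypes 95 genes were called higher in both media (48.9 expected of independent lists) and 21 lower (0.825 expected), and after centring 123 higher (31.5 expected) and 378 lower (60.5 expected), in comparisons that share no library.

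Mitochondrial transcripts took 1.18 ± 0.137% of the TPM in wild type on MS, 1.03 ± 0.152% in wild type in NaCl, 1.54 ± 0.173% in sos2-2 on MS and 1.42 ± 0.0843% in sos2-2 in NaCl (SD, n = 3, 3, 2 and 3). The neighbour MIR859 of MIR774a gave miR859 values that were called higher as a family in sos2-2 in NaCl (0.66, SE 0.15).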
